A study of Homo sapiens with 4 samples.

How the data were processed

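The series holds 10x Xenium in situ measurements of the human nucleus accumbens, with 1 fresh frozen section from each of 4 donors. Xenium images a fixed panel of genes in tissue by cycles of fluorescent decoding and assigns each decoded transcript to a segmented cell. Per the labels, the panel joined a 266-gene base set with a 100-gene custom set aimed at D1 islands and at genes with gradients across the region. The donors form 1 group, so every comparison was made between classes of cells within donors, and donors 1 to 4 are named by replicate number only.

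The deposited matrices hold whole-number transcript counts per feature and cell, not normalized. The deposited feature and barcode tables, whose entries are names and other than counts, list 541 features per matrix. They comprise 366 genes, 20 negative control probes, 41 negative control codewords, 61 unassigned codewords and 53 deprecated codewords. The decoding software, its quality threshold and the segmentation method are not given in the sources used here, and the deposited tables hold no cell positions. Of the 366 genes, 2 on the sex chromosomes were left out on loading and not analysed. Of the other 364 gene symbols, 363 were found in the reference gene table, and 0 of the Ensembl identifiers were. Gene names are therefore those of the files.

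The total over the 364 genes was 57535163 and 73834035 transcripts in donors 1 and 2, and 13502734 and 13339093 in donors 3 and 4. Median transcripts per cell were 176 and 173 in the deeper pair and 38 and 39 in the shallower pair. Cells with at least 20 panel transcripts were kept, which left 165957 of 172722, 208967 of 228127, 134642 of 195980 and 132692 of 188503 cells in donors 1 to 4. Nothing in the labels gives a batch, so donors 1 and 2 and donors 3 and 4 were treated as 2 depth pairs, and values within each pair were computed after the depths were seen.

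Cells were clustered on the 102 panel genes of 18 marker lists that were set before the data were examined. Counts were scaled to 100 per cell, log-transformed with an added 1, centred per donor, divided by the gene SD with a floor of 0.3 and limited to 6 SD. Principal components (25) of an equal sample of 15000 cells per donor gave a graph of 20 nearest neighbours, which was split with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Every other cell took the cluster most frequent among its 15 nearest reference neighbours. Medium spiny neuron-like cells were clustered again, with 6000 cells per donor, 15 components and resolution 0.4. A cluster took the name of a class, written X-like, when at least 3 markers of that class were raised by log2 1 or more over the mean of the other clusters, at least 1 was among its top 10 genes, its leading marker belonged to that class and fewer than 3 markers of another cell family were among its top 20 genes. In the second clustering the limit was log2 0.5, and at least as many markers of the class as of any other neuronal or glial list had to be among the top 10. The class names open to it were D1-like, D2-like and D1-island-like. A list for D1 and D2 hybrid neurons was among the marker lists, but it gave no name. Other clusters kept their number. The resolution of the second clustering, the pseudocounts of the fold (0.0001 and 0.001 of all transcripts) and the rule on markers of another class among the top genes were settled after the leading genes of the clusters had been seen, before any gene was tested. Cells were segmented in tissue and no doublet caller was run. A small medium spiny neuron-like cluster with glial genes among its top genes was kept apart, and an alternative left out cells with over 10% of their transcripts from glial and vascular marker lists.

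Raw counts were summed per donor and class and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Levels are CPM, counts per 1000000 panel transcripts after TMM scaling, and codeword rates are given without that scaling. The 262 panel genes outside every marker list were tested, because the marker genes had made the classes. Both sums of a comparison came from the same donor, so the design held the donor as a block, and the pairing follows from the tissue itself. Each class was also set against the unweighted mean of the other named classes in 1 fit. Of 17 gene lists set before the data were examined, 14 had tested members and 3 had none, and lists of at least 3 members were also tested with fry (limma 3.58.1), adjusted by Benjamini-Hochberg over the 8 lists tested per comparison. Fry asks whether the members move one way on balance and does not compare the list with other genes.

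Named genes followed a rule set before the data were examined. It took the 10 highest and 10 lowest log2 fold changes among called genes with the same sign in all 4 donors and at least 50 transcripts in the higher class of every donor. To these it added every tested opioid, striosome-associated, matrix-associated and shell-associated gene. For medium spiny neurons against interneurons it took 5 per direction, and for each class 3. Of the genes so named, 1 is left out of the text and the plots.

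On simulated counts drawn from the gene means and depths of each donor with 1 mean dispersion per comparison, with 200 changed genes over 4 runs per comparison, the test recovered 88%, 49% and 36% of 1.5-fold changes in the D1-like against D2-like, island and interneuron comparisons. It recovered 100%, 94% and 93% of 2-fold changes, and it called 0.590%, 0.708% and 0.590% of unchanged genes. The leading axis within D1-like and D2-like cells was the first principal component of the log values of the 262 genes in each donor. It was set against cells whose gene values had been shuffled within 20 depth bins. Negative control counts per cell gave the background.

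Alternatives covered the fit without the donor block, DESeq2 1.42.0, DESeq2 size factors, scaling by cell number, no low-count filter, at least 50 transcripts per cell, cells low in glial transcripts, clusters from all panel genes, classes and counts from separate random parts of the transcripts, cells thinned to 20 transcripts, and each donor left out. Comparisons within depth pairs and for single clusters were added after the data had been seen. For the island comparison, cells of both classes were also drawn at random to equal numbers per bin of 0.25 log2 transcripts in each donor. The transcripts that glial and vascular cells could bring were the sum over 7 such classes of the marker level in the class where a gene was higher, as a share of that in the source class, times the source's level of the gene. Figures were drawn with matplotlib 3.10.9.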

Results

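The nucleus accumbens, the ventral part of the striatum, was measured in 1 section from each of 4 donors with an in situ gene panel. The custom part of the panel was aimed at D1 islands, compact groups of small dopamine D1 receptor neurons in the ventral striatum, and at genes graded across the region. After the removal of cells with under 20 panel transcripts, the kept cells had a median of 188, 198, 62 and 62 transcripts in donors 1 to 4. The 4 donors thus formed a deeper and a shallower pair, and values within each pair are given for some results. A deeper section counts more transcripts per cell and carries less counting error.

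Medium spiny neuron-like cells, the GABAergic projection neurons of the striatum, made up 20.5% ± 2.71 (SD, n = 4) of the kept cells. D1-like cells, with the opioid peptide gene PDYN leading, made up 7.41% ± 1.11, and D2-like cells, with PENK, ADORA2A and GPR6 leading, made up 7.32% ± 1.07 (SD, n = 4). The marker gene DRD1 stood at 21912 ± 5552 CPM (counts per 1000000 panel transcripts) in D1-like and 596 ± 365 in D2-like cells, and DRD2 at 321 ± 51.2 and 15121 ± 1816 (SD, n = 4). The ratio of D1-like to D2-like cells was 1.02 ± 0.121, with donors between 0.941 and 1.20. It was 1.03 ± 0.122 with at least 50 transcripts per cell and 1.06 ± 0.116 with classes from a random part of the transcripts. Thinning each cell to 20 transcripts before clustering, far below the median of D1-like cells in any donor (186 or more), changed it. D1-like cells then made up 13.2% and D2-like cells 2.69%, a ratio of 4.88 ± 0.446 (SD, n = 4 for each). D1-island-like cells, with markers such as RXFP1, FOXP2, GABRQ and CPNE4, made up 3.99% ± 1.24 of the kept cells and 19.2% ± 4.33 of the medium spiny neurons (SD, n = 4). They came as 2 clusters, 2.01% ± 0.658 and 1.98% ± 0.586 of cells, and the second had 3 raised island markers and, against the other medium spiny neuron-like clusters, 0 raised markers from the D1 list and 2 from the D2 list. DRD1 stood at 20285 ± 4310 CPM in D1-island-like and 23623 ± 4461 in other D1-like cells (SD, n = 4). Medium spiny neuron-like clusters that reached no name held 1.76% ± 0.356 of cells, and the cluster mixed with glial genes held 0.521% ± 0.314. The latter averaged 0.255% in the deeper and 0.788% in the shallower pair.

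Astrocyte-like cells (17.3% ± 1.39) and oligodendrocyte-like cells (17.1% ± 4.70) were the largest glial classes, followed by microglia-like cells (8.84% ± 0.900) and oligodendrocyte precursor-like cells (6.39% ± 1.75, SD, n = 4 for each). Endothelial cell-like cells made up 4.61% ± 1.17, interneuron-like cells 4.14% ± 0.748, fibroblast-like cells 3.87% ± 0.912, excitatory neuron-like cells 3.68% ± 1.47 and perivascular macrophage-like cells 1.18% ± 0.490. Without cell positions, cells of tissue bordering the nucleus accumbens could not be told apart, and any such cells enter these shares. Clusters without a class name held 11.9% ± 5.28 of cells, from 6.63% to 19.0% between donors. The minimum of 20 transcripts kept 96.1% and 91.6% of cells in the deeper donors against 68.7% and 70.4% in the shallower ones, and it can set part of these shares. The D1-island-like share averaged 4.89% in the deeper pair and 3.09% in the shallower pair, and the excitatory neuron-like share 2.64% and 4.73%. With at least 50 transcripts per cell, interneuron-like cells made up 7.86% in place of 4.14%, and fibroblast-like and perivascular macrophage-like clusters were not found. With clusters from all panel genes, fibroblast-like cells made up 0.914% in place of 3.87% and interneuron-like cells 2.98%. With each cell thinned to 20 transcripts, D1-island-like cells made up 2.39% in place of 3.99%, excitatory neuron-like cells 2.14% in place of 3.68%, astrocyte-like cells 11.98% in place of 17.3%, unnamed medium spiny neuron-like clusters 5.66% in place of 1.76% and other clusters without a name 23.8% in place of 11.9%.

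**Figure D1:**
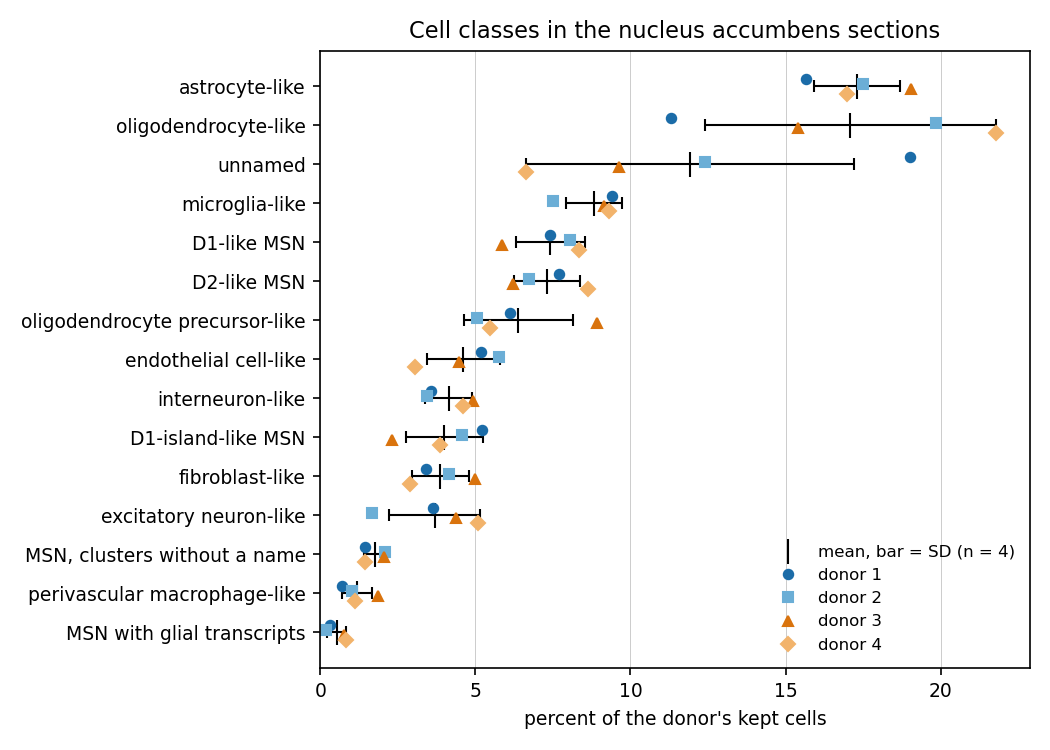
Share of the kept cells in each class, in percent of the donor's kept cells. Each marker is 1 of the 4 donors, the tick is the mean and the bar the SD. Medium spiny neuron-like classes reached 7.41% (D1-like), 7.32% (D2-like) and 3.99% (D1-island-like) on average.

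Negative control probes, which have no target in the tissue, averaged 2.31 ± 1.84 counts per 1000 cells and probe (SD, n = 4), and panel genes averaged 915, 889, 189 and 194 counts per 1000 cells and gene in donors 1 to 4. Of the 364 genes, 351, 349, 362 and 361 in donors 1 to 4 were counted more often than the highest control probe of the same section.

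The leading genes of each class were taken from outside the marker lists. TNC, an extracellular matrix glycoprotein, reached 7609 ± 1072 CPM in astrocyte-like cells (SD, n = 4), 11.4-fold over the next highest class, ahead of SPON1 and PAX6. CLDN11, a tight junction protein of myelin, reached 47622 ± 16257 in oligodendrocyte-like cells, 12.8-fold over the next class, beside KLK6 and CNTN2. PTPRZ1, a receptor phosphatase of glial progenitors, reached 120975 ± 18526 in oligodendrocyte precursor-like cells, beside ATP2C2 and BCAN, though PTPRZ1 was only 2.42-fold and BCAN 2.23-fold over astrocyte-like cells. The Fc receptor gene FCGR3A, a marker of phagocytes, reached 12666 ± 6875 in microglia-like cells, with FCGR1A and the integrin ITGAX. MS4A6A led perivascular macrophage-like cells at 19038 ± 1944, with TGFBI and the class II antigen gene HLA-DMB, of which MS4A6A was 2.98-fold and HLA-DMB 1.31-fold over microglia-like cells. KLF2 and KLF4, transcription factors of the vessel lining, and RNF144B led endothelial cell-like cells, with KLF2 at 19062 ± 4767. LAMA2, a laminin chain, and NR2F2 and PHLDB2 led fibroblast-like cells, with PHLDB2 1.84-fold over endothelial cell-like cells. C1QL3, a secreted synaptic protein, reached 25748 ± 11879 in excitatory neuron-like cells, 19.4-fold over the next class, with HS3ST2 and CLSTN2. NXPH2, PNOC (log2 5.20 over the mean of the other classes, and 4.61 without donor 4) and MEPE led interneuron-like cells, and ONECUT2, COCH and ANO3 led medium spiny neuron-like cells. Per class, between 48 (oligodendrocyte-like) and 111 (interneuron-like) of the 262 tested genes were called above the mean of the other classes, 861 class and gene pairs in all.

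**Figure D2:**
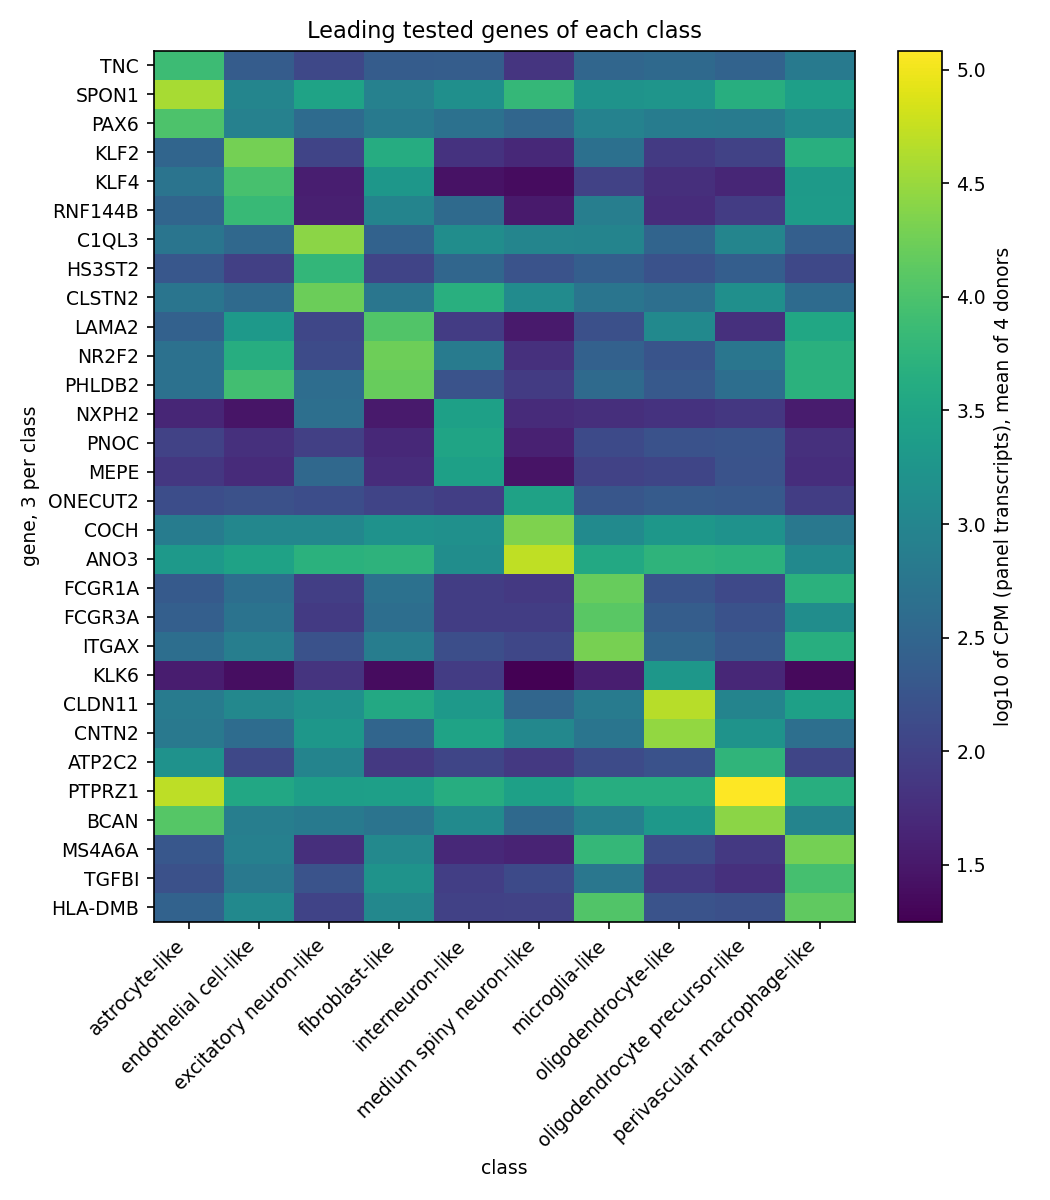
Levels of the 3 leading tested genes of each class, as log10 of CPM (colour, mean of 4 donors), with classes as columns and genes as rows. TNC, for example, reached 7609 CPM in astrocyte-like cells and 668 in the next highest class.

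The comparison of D1-like with D2-like cells asked which panel genes beyond the classical markers part the main output neurons of the striatum. CXCL14, a chemokine gene, stood at 7518 ± 5010 CPM in D1-like and 430 ± 65.4 in D2-like cells (SD, n = 4), a log2 fold change of 3.85 ± 0.42 (SE). ARHGAP36 was 7.47-fold higher in D1-like cells (log2 2.90 ± 0.28), SEZ6L 6.67-fold (2.74 ± 0.17), and RELN, which encodes the extracellular glycoprotein reelin, 6.13-fold (2.62 ± 0.07). OPRD1, the delta opioid receptor, stood at 1480 ± 762 CPM in D2-like and 99.3 ± 73.0 in D1-like cells (log2 -4.01 ± 0.36). HTR2A, a serotonin receptor, was 5.24-fold higher in D2-like cells, and HS3ST4 and NDST4, enzymes that modify heparan sulfate, were 4.88-fold and 4.24-fold higher there. NDST4 in D1-like cells was above the highest control probe of the class in 2 of 4 donors, as was CD86, so the folds of these genes are not exact.

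Of the 262 tested genes, 43 were higher in D1-like and 43 in D2-like cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The other leading genes of D1-like cells were SEMA5B (log2 2.16), the contactin-associated gene CNTNAP3B (1.79), the neuropeptide FF receptor gene NPFFR2 (1.75), RPRM (1.54), the prohormone convertase gene PCSK1 (1.48) and the adrenoceptor gene ADRA1A (1.43). Those of D2-like cells were the calcitonin receptor gene CALCR (-1.93), ALK (-1.71), CD86 (-1.62), the transcription factor gene SOX2 (-1.17), and the mu opioid receptor gene OPRM1 (-1.08). By the rule that named them, these leading genes had the same sign in 4 of 4 donors. Their adjusted p ran from 6.41e-06 to 0.00902 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of those higher in D1-like cells, some stood higher still in D1-island-like cells. SEMA5B reached 2868 CPM there against 217 in other D1-like cells, and RPRM 6195 against 287. NPFFR2 (log2 3.50), SEZ6L (2.94) and CXCL14 (1.76) were also higher there, while RELN, ARHGAP36, CNTNAP3B, PCSK1 and ADRA1A were lower. Whether island cells placed in the D1-like class gave part of these calls was not tested. What glial and vascular cells could bring was not computed for this comparison. SOX2 stood at 487 CPM in D2-like and 216 in D1-like cells. In D1-island-like cells, glial and vascular cells could bring 461 CPM of it. All 86 calls held in cells with at most 10% of transcripts from glial and vascular marker lists.

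Among 5 opioid genes, 2 were lower in D1-like cells (OPRD1 and OPRM1), 0 were higher and 3 did not pass, with the same 2 when adjusted over the list alone. The values that did not pass were 0.08 for PNOC, -0.11 for OPRK1 and -0.23 for OPRL1, the last called with DESeq2 (-0.22) and without donor 3 (-0.26). All 3 serotonin receptors were lower in D1-like cells, over all genes and adjusted over the list alone (HTR2A -2.39, HTR7 -0.73 and HTR2C -0.22), and with any 1 donor left out 2 of the 3 were called. Without the donor block, or within the shallower pair, 1 of the 3 was called. Within the deeper pair 1 of the 5 opioid genes was called. Of 10 neuropeptide and neuropeptide receptor genes, 4 were higher (PCSK1, NPFFR2, PCSK6 and NPY1R) and 1 lower (CALCR), likewise adjusted over the list alone. Its median log2 of -0.10 and mean of 0.16 differed in sign, and fry pointed upward.

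Of 17 axon guidance and adhesion genes, 5 were higher and 3 lower, and 7 and 3 adjusted over the list alone, with NRP1 at 1.01 and NTNG1 at -1.07. Without donor 1, 2 or 4, 5 of the 17 were called in place of 8. Of 10 extracellular matrix genes 2 were higher (NPNT 0.65 and ADAMTS12 0.43) and 2 lower (COL12A1 -1.08 and SPON1 -0.30), and of 12 transcription factors 1 was higher (SOX4 0.43) and 5 lower, in both cases with equal counts adjusted over the list alone. Without donor 2 or 4, 2 of the 10 extracellular matrix genes were called in place of 4. Without the donor block the calls fell to 0 for extracellular matrix, from 6 to 2 for transcription factors, from 8 to 3 for axon guidance and from 5 to 2 for neuropeptide genes. Within the shallower pair they fell to 1, 1, 2 and 2, and within the deeper pair to 2 for extracellular matrix and 3 for transcription factors. Against the larger D2-like cluster alone 2 extracellular matrix genes were called. Of 4 shell-associated genes, ARHGAP6 (0.35) and CRYM (0.21) were higher, CALCR was lower and CARTPT (-0.12) did not pass, with equal counts adjusted over the list alone. The list had a median of 0.04 and a mean of -0.37, and fry pointed downward. CALB1, associated with the striatal matrix, was lower (-0.38), SEMA3E of the same list stood at 0.07, and SEMA5B was the 1 tested striosome-associated gene. KCNH5, a potassium channel gene, was higher (0.59), a call lost without donor 1, 2 or 4 (0 calls in its list), and GRIN2A, a glutamate receptor subunit gene, lower (-0.60). The GRIN2A call was lost without the donor block (-0.60), within either pair alone (-0.52 deeper, -0.68 shallower) and against the larger D2-like cluster alone (-0.20), and KCNH5 was also not called without the block (0.50), with at least 50 transcripts per cell (0.57), with clusters from all panel genes (0.47) or within either pair alone. GABBR2 (0.18) and the dopamine genes DRD5 (0.07) and TH (-0.27) did not pass, and neither did the 7 stress and reactive glia genes, though DESeq2 called 1 dopamine and 2 stress genes and 1 dopamine gene was called against the larger D2-like cluster alone. These small lists gave equal calls when adjusted over the list alone.

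Fry found a shift on balance for the serotonin receptors (adjusted p = 0.00773), axon guidance (0.00866), opioid (0.00945), shell-associated (0.0254), neuropeptide (0.0457) and transcription factor lists (0.0457, Benjamini-Hochberg adjustment over 8 lists). It found none for the extracellular matrix (0.124) or stress lists (0.133).

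Without the donor block 21 genes were called in place of 86, with RPRM (1.85), CALCR (-1.90), CD86 (-1.71), CALB1 (-0.38), ARHGAP6 (0.35) and CRYM (0.21) no longer past the test, and 16 were called within the shallower pair alone, against 58 within the deeper pair, where CXCL14 (3.81), RPRM (1.32), ARHGAP6 (0.29) and OPRD1 (-4.22) did not pass. Within the shallower pair the genes that did not pass included ARHGAP36 (3.09), SEMA5B (1.72), NPFFR2 (1.70), RPRM (1.78), ADRA1A (1.15), HS3ST4 (-2.48), NDST4 (-1.96), ALK (-1.40), CD86 (-1.75), ARHGAP6 (0.42) and CRYM (0.19). The D2-like class joined 2 clusters, and against the larger one alone ALK stood at 0.42 in place of -1.71 while CD86 (-0.02), ARHGAP6 (0.22) and CRYM (0.07) no longer passed, and ARHGAP6 also lost its call without donor 1 (0.40), donor 2 (0.36) or donor 3 (0.26).

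**Figure D3:**
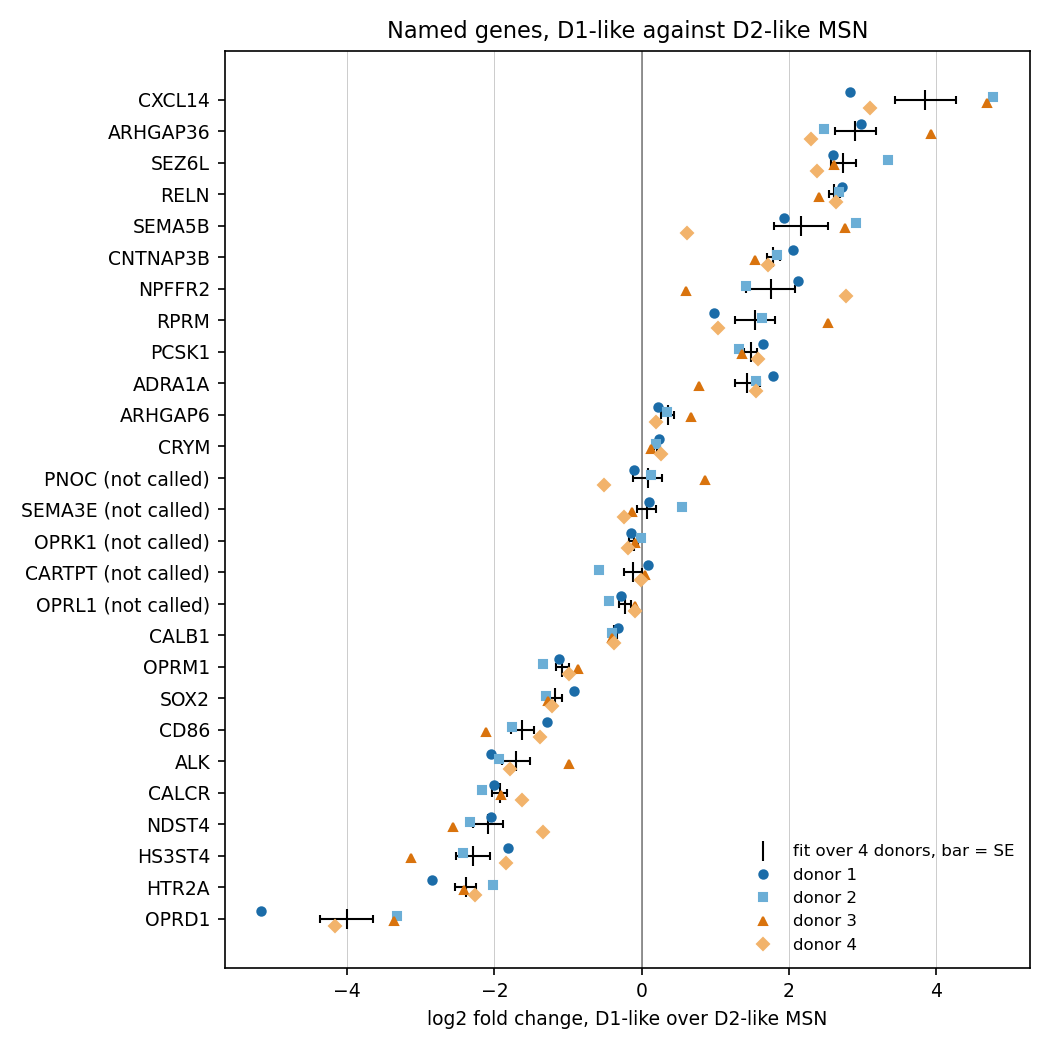
Log2 fold change of the named genes, D1-like over D2-like medium spiny neurons (positive values are higher in D1-like cells). Markers are the 4 donors, ticks the estimate over donors and bars its SE. The estimates run from 3.85 for CXCL14 to -4.01 for OPRD1.

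The custom panel was aimed at D1 islands, and the second comparison set D1-island-like against the other D1-like cells. TRHDE, which encodes the enzyme that degrades thyrotropin-releasing hormone, stood at 2871 ± 283 CPM in D1-island-like and 37.4 ± 9.46 in other D1-like cells (SD, n = 4), 78.9-fold higher. CLSTN2, a synaptic calsyntenin gene, was 44.3-fold higher and VWC2L 41.5-fold higher. These values average 2 unlike clusters: TRHDE was alike in both (log2 0.20, not past the test), while CLSTN2 stood at 496 CPM in the first and 9983 in the second and VWC2L at 236 and 6617. COCH, which encodes a secreted extracellular protein, stood at 440 ± 109 in D1-island-like and 20346 ± 2141 in other D1-like cells (SD, n = 4), a log2 fold change of -5.56 ± 0.17 (SE). RELN was 38.9-fold and ARHGAP36 31.5-fold lower in D1-island-like cells.

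Of 262 tested genes, 71 were higher and 80 lower in D1-island-like cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Part of the panel had been chosen for D1 islands, so this share does not extend to genes outside the panel. The other leading genes were RPRM (log2 4.66), TGFBI (4.48), the stress peptide gene CRH (4.36, and 4.96 without donor 3), ALK (4.35), the substance P receptor gene TACR1 (4.14), SEMA5B (4.02) and NDST4 (3.99). TGFBI came mainly from the first cluster (807 CPM against 48.2 in the second), as did CRH (1776 against 179). In other D1-like cells TGFBI and PNOC were above the highest control probe of the class in 1 of 4 donors and TRHDE, CRH and NDST4 in 2 of 4, so their folds are not exact. TACR1 stood at 3.50 in the deeper and 4.81 in the shallower pair, and HTR2C, among the lowest, at -4.14 and -2.74. The other lowest genes were CNTNAP3B (-4.66), SMOC2 (-4.16), CALB1, which encodes the calcium-binding protein calbindin (-3.94), the utrophin gene UTRN (-3.56), the serotonin receptor gene HTR2C (-3.44), MCTP2 (-3.34) and the cadherin gene CDH6 (-3.34). By the rule that named them, all 20 had the same sign in 4 of 4 donors. Their adjusted p ran from 2.60e-06 to 0.00035 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

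The opioid genes went both ways. OPRM1 stood at 6447 ± 1455 CPM in D1-island-like and 1822 ± 295 in other D1-like cells (SD, n = 4), 3.51-fold higher, and OPRD1 was 5.51-fold higher. OPRK1, the kappa opioid receptor, was 5.82-fold lower, at 395 ± 38.7 against 2303 ± 362. PNOC was 1.33-fold higher (log2 0.41) near its low level of 36.7 ± 12.8 CPM, and its call was lost without donor 1 (0.41) or donor 2 (0.47), without the donor block (0.42), within the shallower pair (0.54), in the first island cluster alone (0.20), with separate random parts of the transcripts (0.46) and with scaling by cell number (0.19). In all, 3 of 5 opioid genes were higher, 1 lower and 1 did not pass (OPRL1, -0.11), with equal counts adjusted over the list alone.

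Of 4 shell-associated genes, ARHGAP6 (-2.30), CRYM (-1.99) and CALCR (-1.52) were lower and CARTPT (-0.20) did not pass, though it was called (-0.75) when the unnamed clusters joined the D1-like class, and CALCR did not pass within the deeper pair alone (-1.20) or without the donor block (-1.46). Both matrix-associated genes, CALB1 and SEMA3E (-1.60), were lower, and SEMA5B of the striosome list was higher, with equal calls for these lists adjusted over the list alone. Of 10 neuropeptide and receptor genes, 5 were higher (CRH, TACR1, NPFFR2 3.50, CALCRL 2.01 and CRHBP 0.36) and 4 lower (among them PCSK6 -1.95 and NPY1R -1.53). Of 17 axon guidance and adhesion genes 6 were higher, with NTNG1 at 2.78, and 10 lower, with the netrin receptor gene DCC at -3.29. Of 10 extracellular matrix genes 2 were higher (THBS1 2.03 and SPON1 1.03) and 7 lower, with ADAMTS12 at -2.24. Of 12 transcription factors 4 were higher, with SOX2 at 2.61 and SOX11 at 1.73, and 2 lower, with TSHZ2 at -1.86. These 4 lists had equal counts adjusted over the list alone. Without the donor block 5 neuropeptide genes were called in place of 9 and 10 axon guidance genes in place of 16, the latter also within the shallower pair, and within the deeper pair 5 extracellular matrix genes in place of 9.

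HTR2A was higher (1.98), HTR2C lower and HTR7 (-0.08) did not pass. GRIN2A (1.54), GABBR2 (1.44) and KCNH5 (1.86, and 0.49, not past the test, when the unnamed clusters joined the D1-like class) were higher, DRD5 (-0.20) and TH (-0.18) did not pass, and 0 of 7 stress and reactive glia genes passed, each with equal calls adjusted over the list alone. Other settings gave calls in these lists: 2 stress genes for the second island cluster alone, 1 when the unnamed clusters joined the D1-like class, and 1 stress and 1 dopamine gene with scaling by cell number. Within the deeper pair 1 serotonin receptor was called in place of 2. Fry found a shift on balance downward for the shell-associated list (adjusted p = 0.0119) and axon guidance (0.0178), and upward for the opioid (0.0254) and transcription factor lists (0.0256, Benjamini-Hochberg adjustment over 8 lists). It found none for the extracellular matrix (0.0854), neuropeptide (0.123), serotonin (0.196) and stress lists (0.828), and the stress list had a median of 0.05 and a mean of -0.02 with fry pointing downward.

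Without the donor block 97 genes were called in place of 151. Scaling by cell number gave 59 higher and 103 lower in place of 71 and 80, with the median of all tested genes at -0.28 in place of -0.07, and CARTPT stood at 0.56 for the first island cluster alone and at -2.26 for the second alone.

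**Figure D4:**
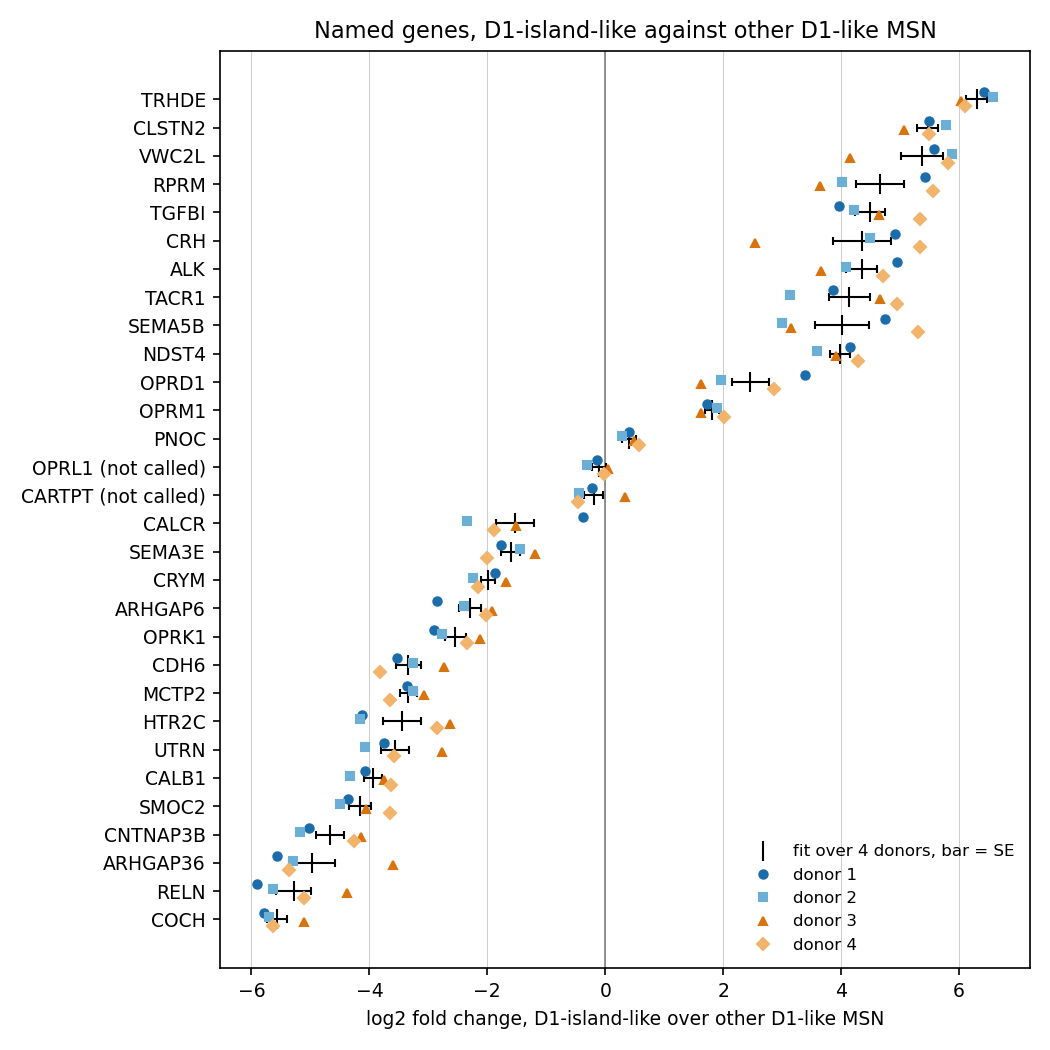
Log2 fold change of the named genes, D1-island-like over other D1-like medium spiny neurons (positive values are higher in D1-island-like cells). Markers are the 4 donors, ticks the estimate over donors and bars its SE. The estimates run from 6.30 for TRHDE to -5.56 for COCH.

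Medium spiny neuron-like cells were also set against interneuron-like cells, the local neurons of the striatum. Of the 25855 interneuron-like cells, 5112 were in a cluster led by SLC5A7, MEPE, NGFR, LHX8 and SLC18A3. MEPE and NGFR, named below, were thus leading genes of that cluster and not of the class as a whole. ANO3, which encodes an anoctamin membrane protein, stood at 49600 ± 7911 CPM in medium spiny neuron-like and 1096 ± 407 in interneuron-like cells (SD, n = 4), a log2 fold change of 5.57 ± 0.20 (SE). CRYM, a thyroid hormone binding protein, was 37.4-fold higher, ONECUT2 37.2-fold, ADAMTS3 34.2-fold and SMOC2 22.6-fold. PNOC, the precursor of the opioid-like peptide nociceptin, stood at 2553 ± 482 in interneuron-like and 39.3 ± 8.78 in medium spiny neuron-like cells (SD, n = 4). MEPE (log2 -6.63), the neurotrophin receptor gene NGFR (-5.67), NXPH2 (-5.45) and the incretin receptor gene GLP1R (-5.45) were the other lowest genes. In medium spiny neuron-like cells MEPE was above the highest control probe in 1 of 4 donors, GLP1R in 2 and PNOC and NGFR in 3, so these folds are not exact. The depth pairs differed for MEPE (-5.93 deeper, -7.57 shallower), NGFR (-6.63 and -4.63) and GLP1R (-6.05 and -4.75).

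Of 262 tested genes, 111 were higher in medium spiny neuron-like and 94 in interneuron-like cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. OPRM1 (2.38), OPRK1 (2.69) and OPRL1 (1.88) were higher in medium spiny neuron-like cells and OPRD1 (-0.51) lower, so with PNOC 3 of 5 opioid genes were higher and 2 lower. Of 17 axon guidance genes 11 were higher and 5 lower, and of 10 extracellular matrix genes 6 were higher and 2 lower, with equal counts for these 3 lists adjusted over the list alone. Of 12 transcription factors 7 were higher in interneuron-like cells, among them NR2F2 (-3.05) and PROX1 (-2.66), and 4 lower, likewise adjusted over the list alone. In cells with at most 10% of transcripts from glial and vascular marker lists only 6 of the 12 were called, 5 higher and 1 lower in interneuron-like cells, and 7 of the 12 against the KIT and TAC3 cluster or the SLC5A7 and LHX8 cluster alone.

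Of 10 neuropeptide and receptor genes, 4 were higher in medium spiny neuron-like cells (CALCRL 3.45, NPY1R 2.78, CARTPT 2.31 and NPFFR2 1.77) and 3 lower (CRH -3.05, TACR1 -2.11 and CRHBP -1.92). Of 4 shell-associated genes 3 were higher, and all 4 adjusted over the list alone, where CALCR (0.75) joined CRYM, CARTPT and ARHGAP6 (2.05). Both matrix-associated genes, SEMA3E (3.84) and CALB1 (2.26), and the striosome-associated SEMA5B (1.58) were higher. SEMA5B did not pass against the KIT and TAC3 cluster alone (-0.22), against 3.77 and 5.05 for the NPY and SST and the SLC5A7 and LHX8 clusters, and against the last 1 of the 2 matrix-associated genes was called. HTR2C (3.46) and HTR2A were higher and HTR7 (-0.06) did not pass. KCNH5 (1.05) and TH (1.58) were higher. KCNH5 stood at 0.28, not called, with at least 50 transcripts per cell, and at -0.63 against the VIP and CCK cluster alone. GABBR2 (-1.58) and DRD5 (-1.97) were lower, though GABBR2 was not called against the SLC5A7 and LHX8 cluster alone (-0.20). The DRD5 call was lost without donor 3 or 4, without the donor block and against the VIP and CCK cluster alone (1 call in its list in each). GRIN2A (-0.11) did not pass. GRIN2A was lower in cells low in glial transcripts (-0.73) and with scaling by cell number (-0.63), lower against the KIT and TAC3 (-1.58) and VIP and CCK clusters (-0.96) and higher against the NPY and SST (1.05) and SLC5A7 and LHX8 clusters (2.35), so its joined value averages unlike clusters. Of 7 stress and reactive glia genes, 2 were higher (HILPDA 0.78 and CAPG 0.48) and 4 lower, among them CD44 (-0.77), and against the KIT and TAC3 cluster alone 2 of the 7 were called. Apart from the shell-associated list, these lists had equal calls adjusted over the list alone.

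Fry found a shift on balance upward for axon guidance (adjusted p = 7.75e-05) and for the opioid, serotonin, shell-associated and extracellular matrix lists (0.000507 each), and downward for the transcription factors (0.000507) and the stress list (0.0122, Benjamini-Hochberg adjustment over 8 lists). It found none for the neuropeptide list (0.0954).

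Interneuron-like cells with over 10% of transcripts from glial and vascular marker lists made up 36.3% ± 1.45 of their class, against 5.40% ± 2.14 of D1-like and 5.09% ± 1.87 of D2-like cells (SD, n = 4). Without such cells 99 genes were higher and 103 lower, and with scaling by cell number 77 were higher and 118 lower, with the median of all tested genes at -0.34 in place of 0.17. The interneuron-like class joined 4 clusters, and against single ones NGFR stood at 0.14 (the VIP and CCK cluster) or -0.34 (the NPY and SST cluster), MEPE at -0.24 (the KIT and TAC3 cluster) or -0.96 (the VIP and CCK cluster) and NXPH2 at -0.86 (the SLC5A7 and LHX8 cluster), none past the test.

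The panel held genes chosen for gradients, and covariation between cells was described without positions. The first principal component of the 262 tested genes took 14.1% ± 4.32 of the variance in D1-like and 13.5% ± 4.21 in D2-like cells (SD, n = 4), against means of 6.84% and 5.68% in shuffled cells. CALB1, ANO3, CRYM and COCH loaded with the same sign in all 8 combinations of donor and class, at mean loadings of 0.403, 0.359, 0.350 and 0.320, and CXCL14 with the opposite sign in D1-like cells at -0.338. These genes were chosen after their values were seen. The same genes parted D1-island-like from other D1-like cells. COCH (log2 -5.56), CALB1 (-3.94), ANO3 (-2.14) and CRYM (-1.99) were lower there and CXCL14 (1.76) higher. CRYM was also lower in the smaller of the 2 joined D2-like clusters. Whether unlike groups of cells left within a class gave the component, in place of a gradient, was not tested. Loadings were correlated between donors across genes, which are not independent replicates. The mean r over 6 donor pairs was 0.782 in D1-like and 0.925 in D2-like cells. Shuffled cells gave means of 0.472 and 0.833, with single pairs up to 0.933 and 0.957, so neither mean is clear of the shuffled range. With the component of the same cells taken over all 364 panel genes, marker genes included, the mean r was 0.576 in D1-like cells against 0.561 shuffled. The D1-like value is thus not clear of depth and gene level. In D2-like cells the mean r over all panel genes was 0.965 against 0.846 shuffled. Single shuffled pairs reached 0.985, so this mean is not clear of the shuffled range either. In donor 1 the D1-like component correlated with log depth at r = 0.628, against 0.232 to 0.266 in the other donors. With each cell thinned to 20 transcripts the component took 6.12% and 5.99% of the variance, against 5.63% and 5.55% in shuffled cells. Its loadings then correlated between donors at a mean r of 0.798 against 0.684 shuffled in D1-like and 0.782 against 0.396 in D2-like cells. Single shuffled pairs reached 0.862 in D1-like and 0.760 in D2-like cells.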

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

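The comparisons of donor splits and the test for glial and vascular transcripts were chosen after the gene results had been seen, and the other tests here were written down before their results were seen.

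A codeword that the panel lists as deprecated, DeprecatedCodeword_0304, was counted 171 times per 1000 cells, 15.9 to 26.8 times the highest negative control probe of the same section. Its rate was highest in excitatory neuron-like cells in 4 of 4 donors, at 5124 ± 1076 CPM (counts per 1000000 panel transcripts, SD, n = 4), and on average 16.2 times that of the median class, which argues against background decoding as its source. Over 31 clusters its rate followed TBR1 (mean r 0.905), SLC17A7 (0.903) and C1QL3 (0.895). Counts misread from 1 panel gene could keep a steady ratio to that gene, and the steadiest, NEUROD2, still differed 2.65 times between 5 neuronal classes, short of the 3 times set beforehand as excluding it, so this explanation stays open. No biological explanation was tested.

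The genes that parted D1-island-like from other D1-like cells were weighed as a second pattern. Transcripts of neighbouring glial and vascular cells could enter either class, and the astrocyte markers in D1-island-like cells stood at 4.08% ± 0.659 of their level in astrocyte-like cells (SD, n = 4). Of the 151 called genes, 70.2% differed in all 4 donors by more than glial and vascular cells could bring at such marker levels. This was short of the 80% set as excluding it, so this explanation stays open for the other 45, which include none of the named genes. Transcripts of neighbouring neurons were not part of this bound, and CLSTN2, for example, stood at 16502 CPM in excitatory neuron-like cells. D1-island-like cells held fewer transcripts per cell than other D1-like cells, but 90.7% of the called genes were called in the same direction in cells drawn to the same depths within each donor, which argues against that difference as the cause. No biological explanation was tested, since the labels give 1 group.

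With the donor as a block, 8 splits of the class sums part all donor pairs, too few for a share under 0.05, and 1 of 8, the real one, gave as many genes in each comparison. The real splits gave 86, 151 and 205 genes in the D1-like against D2-like, island and interneuron comparisons and the highest other 0 in each. Without the block, 35 splits were possible. For D1-like against D2-like cells, 2 of 35 splits, the real one included, reached the real 21, and the split of the deeper from the shallower donors gave 115, which points to a structure of the samples by depth. For the other comparisons the real values were 97 and 172 and the highest others, again the split by depth, 54 and 15.

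In 83 groups of 4 donors, 4 (4.82%) had 1 donor far from the others, against about 1 in 20 by chance. Microglia-like cells made up 7.49% in donor 2 against 9.16% to 9.40% in the others. The log2 fold change of CARTPT between D1-like and D2-like cells was -0.58 in donor 2 and -0.02 to 0.09 in the others. That of ARHGAP36 between D1-island-like and other D1-like cells was -3.59 in donor 3 and -5.56 to -5.30 in the others. That of PNOC between medium spiny neuron-like and interneuron-like cells was -6.88 in donor 4 and -5.81 to -5.61 in the others.

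Another 6 deprecated codewords were counted above every control probe in all 4 donors, at 79.4, 63.2, 48.9, 21.0, 16.7 and 13.2 counts per 1000 cells. They were highest in oligodendrocyte-like cells, oligodendrocyte-like cells, unnamed medium spiny neuron-like clusters, fibroblast-like, D2-like and excitatory neuron-like cells in that order on average. The same class was highest in 4, 4, 3, 4, 2 and 1 of 4 donors, so the class is not settled for the last 2.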

How the results depend on the processing

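Comparisons within depth pairs and for single clusters were chosen after the data had been seen. Of 864 named-gene values under the alternatives set beforehand, 842 kept their direction and side of the threshold, 15 lost and 2 gained a call and 5 changed sign. Of 294 under the added ones, 258 kept both, 27 lost and 2 gained a call and 7 changed sign. Among the alternatives set beforehand, the fit without the low-count filter tested the same 262 genes and equalled the main fit, so its values could not differ. With clusters from all panel genes, the tested genes themselves helped to make the classes. The pairing of class sums within donors set the count of genes: without the donor block it was 21 in place of 86 (D1-like against D2-like) and 97 in place of 151 (island), and 172 in place of 205 for interneurons. The shallower pair alone gave 16 in place of 86, with 2 donors in place of 4. With each cell thinned to 20 transcripts, named classes held 68.7% of cells in place of 85.8%, D1-like cells 13.2% in place of 7.41%, D2-like cells 2.69% in place of 7.32% (a ratio of 4.88 in place of 1.02), and the leading component 6.12% (D1-like) and 5.99% (D2-like) of the variance. Negative control codewords averaged 0.205 counts per 1000 cells against 2.31 for probes. With at least 50 transcripts per cell, fibroblast-like and perivascular macrophage-like clusters could not be given a value.

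Changes of sign met genes near 0 except where single clusters were used. With donors left out in turn, D1-like against D2-like values ran from -0.044 to 0.23 for PNOC, -0.093 to 0.21 for SEMA3E and -0.19 to 0.037 for CARTPT. PNOC stood at -0.017 with clusters from all panel genes and -0.047 with separate random parts of the transcripts. Within the shallower pair SEMA3E stood at -0.20, CARTPT at 0.00122 and, for the island comparison, OPRL1 at 0.022. ALK stood at 0.42 against the largest D2-like cluster, OPRL1 at 0.018 and CARTPT at 0.56 in the first island cluster alone, and NGFR at 0.14 against the VIP and CCK interneuron cluster. The cause was not tested.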

Other observations

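The comparisons of single clusters here were chosen after the clusters and their values had been seen. The 2 D1-island-like clusters differed from each other in 131 of 261 tested genes, 62 higher and 69 lower in the first, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TGFBI stood at 807 ± 247 CPM in the first and 48.2 ± 25.1 in the second (SD, n = 4), and SCN4B, a sodium channel subunit gene, was 13.6-fold, CARTPT 7.04-fold and SPON1 5.07-fold higher in the first, as was CRH (log2 3.32). VWC2L stood at 6617 ± 1379 in the second and 236 ± 64.8 in the first, and C1QL3 was 24.5-fold, RGS6 21.8-fold and CLSTN2 21.2-fold higher in the second. With donors left out in turn, 95 to 126 genes were called. C1QL3 and CLSTN2 were also leading genes of excitatory neuron-like cells, at 25748 and 16502 CPM, and the second cluster had 0 raised markers from the D1 list. Whether excitatory neurons or their transcripts gave part of its profile was not tested.

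The smaller D2-like cluster (0.536% ± 0.103 of cells, SD, n = 4) differed from the larger in 139 of 261 genes, with 61 higher. ALK stood at 6391 ± 2410 against 132 ± 18.3 CPM, GFRA2 was 24.8-fold higher, and SMOC2 56.3-fold, CNTNAP3B 23.7-fold, ARHGAP6 20.7-fold, OPRD1 19.3-fold and CRYM 17.9-fold lower. The smaller cluster had TAC1 beside GPR6 and DRD2 among its top genes, with 4 raised markers of the D2 list and 1 of the D1 list. Since no hybrid name was open to a cluster, whether it holds D1 and D2 hybrid neurons was not tested. A cluster led by SEMA3E, CARTPT and RXFP2, which reached no name (1.42% ± 0.328 of cells), differed from D1-like cells in 123 of 261 genes, with 67 higher. TAFA1 was 27.4-fold, EPHA5 19.4-fold and RPRM 13.3-fold higher, and CDH6 17.3-fold and ARHGAP36 16.7-fold lower. With donors left out in turn, 113 to 136 and 95 to 117 genes were called.

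Among clusters of other cells without a class name, 1 led by TRPC4, ARHGAP36, SLC17A6, CALB2 and PNOC held 3.67% ± 2.02 of cells (SD, n = 4). Another, led by FOXJ1, SERPINA3, ANXA1, ZBBX and CFAP157, held 1.72% ± 1.53. Its share was 3.75%, 2.02%, 0.327% and 0.769% in donors 1 to 4, so it came mainly from the deeper pair. Its cells had a median of 44, 36, 31.5 and 39 transcripts, against 188, 198, 62 and 62 for all kept cells. FOXJ1 was counted 612712 and 399596 times in donors 1 and 2, against 3024 and 4955 in donors 3 and 4. That gap was wider than the gap in all panel transcripts, and its cause was not tested.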
